A study of Arabidopsis thaliana with 18 samples.

How the data were processed

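The deposited files hold 1 table per library of FPKM for 33602 Arabidopsis loci, in 18 libraries of roots from wild-type seedlings. Seeds were stratified for 48 h at 4 °C, and seedlings grew for 14 days on agar at 23 °C with 16 h of light and 8 h of dark. Per the labels, libraries were strand-specific messenger RNA preparations from RNA of an integrity number of at least 7.0, sequenced on a HiSeq 2500. Groups were taken from the sample names: DMSO control, BPA, BPB, BPE, BPF and BPS, with 3 libraries each.

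Per the file headers, the authors gave gene values as FPKM, which is per kilobase of gene and scaled to the mapped fragments of the library. Per the submitters' processing notes, HISAT2 2.0.4, StringTie 1.3.0 and edgeR were used with the build TAIR10. The notes do not tie a role or settings to each tool, and state neither the annotation release nor a filter. Read counts were not used here, so tests that need counts were not run, and FPKM values were not rescaled for the main results. Totals of the FPKM columns ran from 585990.2 to 614991, and 6446 loci were at 0 in every library. Of the loci, 32835 (97.7%) were matched to the reference gene table of TAIR10.1, and 10654 had a symbol. Reference coordinates served only for transcript lengths behind the fragment totals and for overlaps between loci.

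Fragment totals were recovered from the step between low values. Between 55.6% and 62.6% of values below 2 FPKM that stood for 1 to 5 fragments lay within 0.02 of a whole number of them, against 4.0% for values spread evenly. The 10 genes with the highest values took 2.31% to 3.54% of a library's total. Fragments without molecular identifiers are not independent molecules, so the fragment numbers speak to counting error only.

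Values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 18 libraries were tested, 19484 in all. A linear model with 1 coefficient per group was fitted to all 18 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior (limma-trend). Each compound was compared with the control, and each pair of compounds was compared directly, 15 comparisons in all. P-values are two-sided, were adjusted by Benjamini-Hochberg within each comparison, and were called at an adjusted p below 0.05. The labels name no batch, plate or date, so no batch term was fitted. The median half-width of the 95% interval of a log2 change was 0.40.

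Before the data were examined, 29 gene lists with 661 members by locus were fixed, together with the comparisons, tests, alternatives and the rule for naming genes. They cover redox and detoxification (class III peroxidases, glutathione S-transferases, intracellular scavenging enzymes, NADPH oxidases, UDP-glucosyltransferases, chemical-inducible markers and cytochrome P450s), hormones, stress, nutrients, the cell wall, root hairs, the cell cycle, and tissue other than root. The cytochrome P450 list holds the 251 genes with such a symbol in the reference, of which 143 passed the filter. Each list was compared with all other tested genes by camera in limma with a preset correlation of 0.01, adjusted over lists within a comparison. It was compared again with a correlation estimated from the data. The number of members called is given over all genes tested and adjusted over the list alone. After the data were seen, 3 lists were added (early touch and wound genes, late wound genes, shoot genes outside photosynthesis), as was the list of genes annotated with oxidation reduction. For annotation terms, 160 terms with 15 to 1000 of the 8609 annotated tested genes were compared by one-sided Fisher's exact tests, with that background.

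By the naming rule, each comparison with control gives up to 3 members of each called list and up to 2 of each redox list not called, those with the smallest adjusted p. To these come the 5 largest rises and 5 largest falls without overlap of the groups, which chance gives for 10% of genes with 3 against 3 libraries. Up to 5 rises and 5 falls shared by all 5 comparisons were named, and 2 rises and 2 falls per pair of compounds. The texts give a part of the 299 results so named. Genes named outside the rule are marked as chosen after their values were seen.

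Tests on 19484 simulated independent genes, 200 of them changed, found 69% at a log2 change of 1 and 93% at 2. Of 186 calls 15 were false, and 9 were members of a list of 20 genes shifted by 0.7. Unchanged comparisons gave at most 1 call. The shifted list was called, and 0 of 9 unchanged lists were, which leaves the preset correlation untested. For the shared response, 100 draws (seed 1) simulated unchanged groups with shared controls.

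Alternatives were quantile normalization of the log2 values, limma without an intensity trend, no filter on low values (27156 genes), log2(FPKM + 0.1), replicate number as a block, only the 6 libraries compared, a 2-fold threshold added, and each library left out in turn. For lists, members shared with other lists were removed. For the shared response, the share of genes of the same sign and the correlation over genes with at least 5 FPKM were used. Median scaling, in which each library is shifted to the same median, and the omission of BPB replicate 3 with BPS replicate 3 were added after the data were seen. Where a group is left with 2 libraries, its spread is pooled with that of the other groups. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.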

Results

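Roots of wild-type Arabidopsis thaliana (thale cress) were sequenced as strand-specific messenger RNA libraries after 14 days on agar plates. There were 6 groups of 3 libraries: a dimethyl sulfoxide (DMSO) control and roots grown with bisphenol A (BPA), B (BPB), E (BPE), F (BPF) or S (BPS). Each of these compounds holds 2 phenol rings joined by a bridge. The bridge is a carbon with 2 methyl groups in BPA, a carbon with a methyl and an ethyl group in BPB, a carbon with 1 methyl group in BPE, a plain methylene in BPF and a sulfonyl group in BPS. The protocol names doses of 1, 3 and 10 mg/L, and no label ties a dose to a library, so the compounds are not known to be matched in dose. The title of the series gives the oxidation-reduction process of roots under bisphenols as its subject. The comparisons with control address how root transcripts, those of redox enzymes among them, differ after growth with each compound.

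Depth was similar across the libraries. Fragment totals recovered from the values ran from 15.9 M in BPB replicate 1 to 22.2 M in BPE replicate 3, with a median of 18.4 M. Between 22971 and 24256 of 33602 loci were above 0. Values are FPKM, fragment counts scaled to gene length and to the mapped fragments of the library. A value of 1 FPKM on a transcript of 1.5 kb stood for 23.9 to 33.3 fragments, which speaks to counting error only. Gene values are given as mean ± SD of FPKM with n = 3 libraries per group, and log2 changes are on the log2(FPKM + 1) scale. Adjusted p-values of single genes come from limma with the Benjamini-Hochberg adjustment over 19484 genes, and genes are named by symbol and Arabidopsis locus. Nothing in the labels says that replicates came from separate plates or plants, so the p-values measure the spread between these libraries.

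Samples of 1 group mostly lay near each other in a principal component analysis, with exceptions in BPA, BPB, BPF and BPS. The first component, 36.9% of the variance, placed BPE at -59.5 to -49.6 and BPS at 40.7 to 66.2. BPA replicate 3 lay at 20.3 on it, while BPA replicates 1 and 2 lay at -41.7 and -24.8. On the second component, 25.4% of the variance, BPB replicate 3 lay at -7.44, while BPB replicates 1 and 2 lay at -55.0 and -65.1. On the third, 16.1% of the variance, BPB replicate 3 and BPS replicate 3 lay at 59.9 and 45.2, away from BPB replicates 1 and 2 (-20.5 and 8.02) and BPS replicates 1 and 2 (-35.3 and -12.3). The labels give no sequencing batch or date, so no relation could be recomputed within batches.

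**Figure D1:**
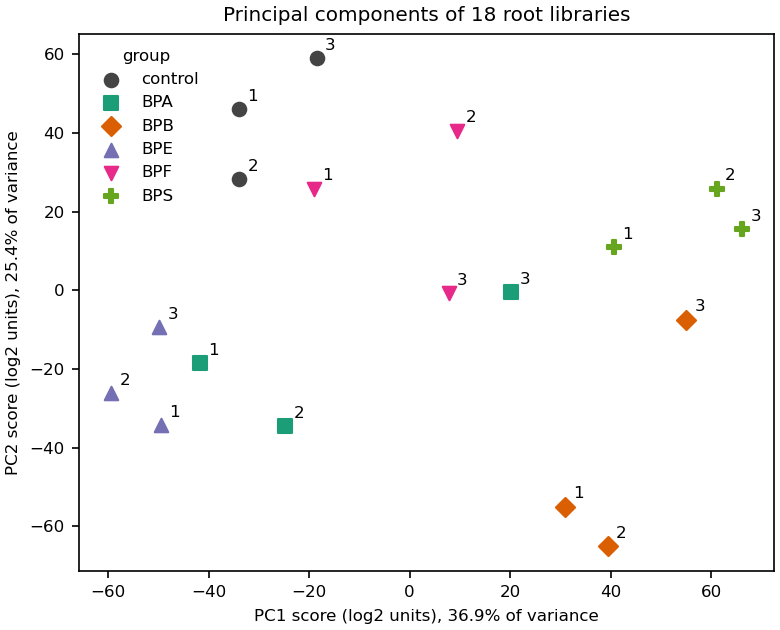
Principal component scores (log2 units) of the 18 libraries over 19484 genes, with PC1 (36.9% of variance) on the x axis and PC2 (25.4%) on the y axis. Each point is 1 library, coloured and shaped by group and numbered by replicate; BPA replicate 3 and BPB replicate 3 lie apart from the other libraries of their groups.

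Every compound was compared with the control, and each pair of compounds was compared directly. Against control, BPB changed 7137 genes (4973 higher, 2164 lower), BPS 4094 (2396 higher, 1698 lower), BPE 2783 (1770 higher, 1013 lower), BPA 2027 (1281 higher, 746 lower) and BPF 270 (138 higher, 132 lower). The balance of directions moved with the scaling: with each library shifted to the same median, the higher genes made up 47.4% for BPB, 43.8% for BPS, 45.1% for BPE, 46.8% for BPA and 40.4% for BPF. Of 145 tests of 29 gene lists against control, camera called 54 at its preset correlation. With an estimated correlation it called 0, the lowest adjusted p being 0.251, and each list's value stands beside its count.

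**Figure D2:**
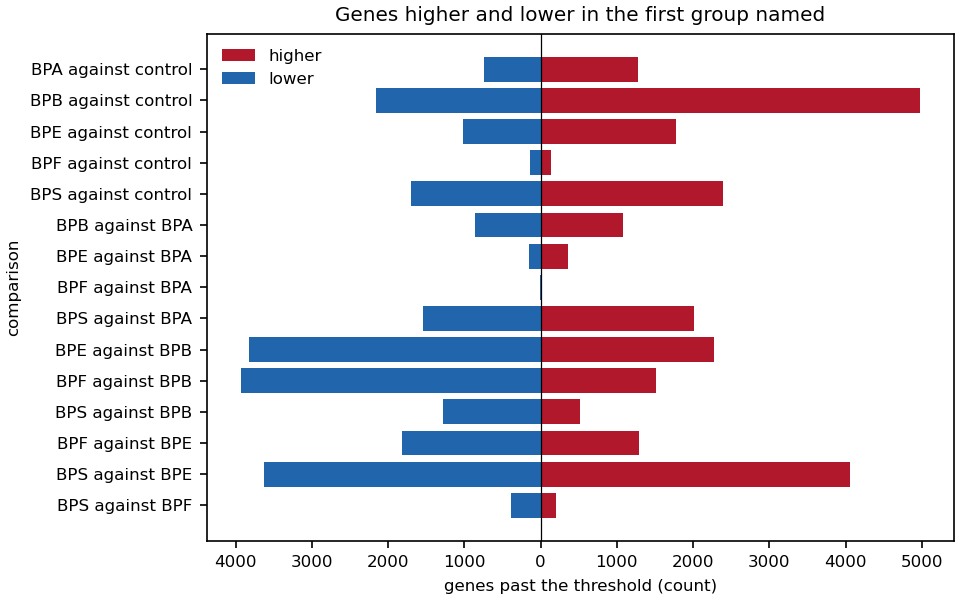
Number of genes past adjusted p 0.05 (x axis, gene count) in each of 15 comparisons (y axis), with genes higher in the first group named drawn to the right and lower genes to the left. BPS against BPE holds 7686 genes and BPF against BPA holds 13.

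In BPA roots, hypoxia genes were lower and photosynthetic shoot markers and water channels higher than in the control. ADH1 (AT1G77120), alcohol dehydrogenase, fell from 313 ± 99.2 to 24.9 ± 8.78 FPKM (SD, n = 3, log2 change -3.60, adjusted p = 0.00615). It was 1 of 11 of 15 measured hypoxia genes that fell (14 adjusted over the list alone), with a median log2 change of -1.73 (camera adjusted p = 1.43e-10, and adjusted p = 0.653 with an estimated correlation). PSBO1 (AT5G66570), of the oxygen-evolving complex of photosystem II, rose from 20.01 ± 7.93 to 72.5 ± 23.4 FPKM. It stood among 18 of 26 photosynthetic shoot markers that rose (19 adjusted over the list alone; median 1.42, camera adjusted p = 2.81e-12, and adjusted p = 0.653 with an estimated correlation). The plasma membrane water channels PIP2;1 (AT3G53420) and PIP1;1 (AT3G61430) rose from 165 ± 26.6 to 466 ± 57.2 and from 80.2 ± 17.2 to 174 ± 20.8 FPKM. Among 19 aquaporins 7 rose and 1, PIP2;5 (AT3G54820, log2 change -1.47), fell (9 and 1 adjusted over the list alone; median 0.25, camera adjusted p = 0.0479, and adjusted p = 0.774 with an estimated correlation).

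Root hair genes were lower with BPA: 4 of 22 fell (11 adjusted over the list alone), the median being -1.04 (camera adjusted p = 2.73e-07, and adjusted p = 0.689 with an estimated correlation). RHS2 (AT1G12950), a root hair specific gene, fell from 380.0 ± 85.5 to 86.4 ± 49.2 FPKM (log2 change -2.26). Of 23 phosphate starvation genes 1 fell (1 adjusted over the list alone; median -0.84, camera adjusted p = 0.000364): RNS1 (AT2G02990), a ribonuclease, from 165 ± 52.0 to 13.5 ± 11.0 FPKM. Of 20 lignin and phenylpropanoid enzymes 1 fell (1 adjusted over the list alone; median -0.44, camera adjusted p = 0.000769), and of 27 Casparian strip and suberin genes 1 fell (0 adjusted over the list alone; median -0.19, camera adjusted p = 0.0208). Among 9 flavonoid genes limma called 0 over all genes and 0 adjusted over the list alone (median -0.30, camera adjusted p = 0.0485). For these 4 lists adjusted p = 0.774 with an estimated correlation. Heat shock genes were lower too, 2 of 14 over all genes (6 fell and 1 rose adjusted over the list alone; median -0.40, camera adjusted p = 0.0105, and adjusted p = 0.653 with an estimated correlation). NIP2;1 (AT2G34390), an aquaporin-like channel, fell from 60.7 ± 26.6 to 2.78 ± 1.14 FPKM, and the nitrate transporter NRT2.1 (AT1G08090) fell from 72.6 ± 39.6 to 2.69 ± 1.52 FPKM (adjusted p = 0.00843, and 0.0514 without BPA replicate 2).

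Redox and detoxification genes moved both ways with BPA, and camera called none of the 7 lists. CYP81D11 (AT3G28740), a cytochrome P450 induced by foreign chemicals, rose from 48.6 ± 4.21 to 163 ± 26.4 FPKM. The glucosyltransferase UGT72E1 (AT3G50740) rose from 5.77 ± 0.707 to 23.2 ± 6.32 FPKM while UGT71C3 (AT1G07260) fell from 21.9 ± 4.18 to 11.7 ± 0.279 FPKM. Leaving out a library moved the count of 2027 genes to 382 without control replicate 1, 569 without control replicate 3 and 245 without BPA replicate 2. It also ended list calls. Without BPA replicate 3 these were Casparian strip genes (adjusted p = 0.0703), lignin (0.0597), heat shock (0.0703) and aquaporins (0.184). Without BPA replicate 2 the Casparian strip call ended too (0.170). The flavonoid call ended without control replicates 1 and 3 (0.0770 and 0.0624) and without BPA replicates 1 and 2 (0.169 and 0.0989). Peroxidases were called without control replicate 2 (0.0372).

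In BPB roots, single genes of dehydration and jasmonate response fell by large factors, and every photosynthetic shoot marker measured rose. RD29A (AT5G52310), a dehydration-responsive gene, fell from 812 ± 175 to 6.19 ± 2.75 FPKM (SD, n = 3, log2 change -6.87, adjusted p = 4.06e-06). KIN1 (AT5G15960) fell from 257 ± 57.5 to 3.27 ± 1.63 FPKM, though its sequence is close to that of KIN2 and the reads of such pairs are hard to divide. Both belong to the abscisic acid and dehydration list, of which 7 of 20 fell (7 adjusted over the list alone; median -0.81, camera adjusted p = 1.84e-06, and adjusted p = 0.251 with an estimated correlation). JOX4 (AT2G38240), a jasmonate oxidase, fell from 382 ± 69.9 to 0.615 ± 0.633 FPKM, and AOC2 (AT3G25770), an allene oxide cyclase of jasmonate synthesis, from 88.0 ± 4.35 to 2.11 ± 1.85 FPKM. The jasmonate list had 6 of 21 lower (6 adjusted over the list alone; median -0.81, camera adjusted p = 0.000138, and adjusted p = 0.600 with an estimated correlation), a call lost without BPB replicate 3 (0.0749), where the median was -0.20. All 26 photosynthetic shoot markers rose (26 adjusted over the list alone; median 2.30, camera adjusted p = 3.18e-11, and adjusted p = 0.382 with an estimated correlation), LHCB5 (AT4G10340), a light-harvesting protein, from 6.0 ± 3.1 to 49.4 ± 7.74 FPKM.

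Genes of the phenylpropanoid pathway and of root hairs fell with BPB beside these markers. C4H (AT2G30490), cinnamate 4-hydroxylase, fell from 1040 ± 44.1 to 358 ± 60.4 FPKM. Of 20 lignin and phenylpropanoid enzymes 13 fell (13 adjusted over the list alone; median -0.79, camera adjusted p = 1.09e-07, and adjusted p = 0.251 with an estimated correlation). RHS2 (AT1G12950) fell from 380.0 ± 85.5 to 15.71 ± 5.96 FPKM, and RSL4 (AT1G27740), a regulator of root hair growth, from 16.1 ± 2.96 to 4.98 ± 2.08 FPKM. Their list had 10 of 22 lower (16 adjusted over the list alone; median -1.06, camera adjusted p = 6.94e-08, and adjusted p = 0.382 with an estimated correlation). Hypoxia genes fell in 12 of 15 cases (13 adjusted over the list alone; median -1.59, camera adjusted p = 1.91e-09), heat shock genes in 9 of 14 with 1 rise (10 and 2 adjusted over the list alone; median -0.89, camera adjusted p = 0.000538) and auxin genes in 7 of 28 with 3 rises (9 and 3 adjusted over the list alone; median -0.17, camera adjusted p = 0.00545). For these 3 lists adjusted p = 0.251 with an estimated correlation. Aquaporins rose, 11 of 19 against 1 fall (11 and 2 adjusted over the list alone; median 0.72, camera adjusted p = 0.00679, and adjusted p = 0.600 with an estimated correlation), a call lost without BPB replicate 3 (0.0567).

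Among redox genes BPB lowered glutathione S-transferases, which conjugate foreign compounds to glutathione. GSTU6 (AT2G29440) fell from 507 ± 127 to 22.0 ± 11.0 FPKM and GSTU26 (AT1G17190) from 651 ± 51.1 to 101 ± 35.0 FPKM, both members of tandem clusters with close copies. Of 37 measured, 11 fell and 4 rose (12 and 4 adjusted over the list alone; median -0.24, camera adjusted p = 0.000754, and adjusted p = 0.251 with an estimated correlation). Class III peroxidases went both ways, 10 of 60 higher and 12 lower (11 and 12 adjusted over the list alone), with a median of 0.0082 and a mean of -0.14. Camera called them lower (adjusted p = 0.0402, and adjusted p = 0.600 with an estimated correlation). The call ended after quantile normalization (0.446) or median scaling (0.210), both with a negative median, and without control replicate 3 (0.0778) or BPB replicate 2 (0.159). APX1 (AT1G07890), ascorbate peroxidase, fell from 409.9 ± 16.0 to 205 ± 23.4 FPKM, and GPX1 (AT2G25080), glutathione peroxidase, rose from 19.4 ± 1.51 to 43.1 ± 5.90 FPKM. The detoxification markers, not called with all libraries, were called lower without BPB replicate 1 (0.0268).

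In BPE roots, flavonoid, root hair and phosphate starvation genes fell, and genes induced by foreign chemicals rose. FLS1 (AT5G08640), flavonol synthase, fell from 61.5 ± 10.6 to 15.2 ± 0.880 FPKM (SD, n = 3, log2 change -1.94, adjusted p = 0.000435), and F3H (AT3G51240) fell from 72.3 ± 10.2 to 22.3 ± 2.49 FPKM. Of 9 flavonoid genes 7 fell (9 adjusted over the list alone; median -1.14, camera adjusted p = 4.49e-09, and adjusted p = 0.371 with an estimated correlation). RSL4 (AT1G27740) fell from 16.1 ± 2.96 to 5.31 ± 2.51 FPKM among 13 of 22 root hair genes that fell (17 adjusted over the list alone; median -1.49, camera adjusted p = 6.08e-11). Phosphate starvation genes fell in 5 of 23 cases (8 adjusted over the list alone; median -1.51, camera adjusted p = 2.68e-08). NIT4 (AT5G22300), a nitrilase, rose from 0.470 ± 0.101 to 6.71 ± 3.04 FPKM and CYP81D11 (AT3G28740) from 48.6 ± 4.21 to 147 ± 33.5 FPKM. They were among 8 of 18 chemical-inducible detoxification markers that rose (11 rose and 1 fell adjusted over the list alone; median 1.05, camera adjusted p = 0.000447). Photosynthetic shoot markers rose in 19 of 26 cases (22 adjusted over the list alone; median 1.38, camera adjusted p = 3.31e-10), PSAL (AT4G12800) of photosystem I from 4.42 ± 1.28 to 17.1 ± 1.90 FPKM. For these last 4 lists adjusted p = 0.538 with an estimated correlation.

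Abscisic acid genes rose with BPE, while the medians of cell cycle and wall-loosening genes were negative. HAI1 (AT5G59220) and PP2CA (AT3G11410), protein phosphatases of abscisic acid signalling, rose from 3.64 ± 1.46 to 29.1 ± 15.8 and from 40.5 ± 8.71 to 109 ± 37.2 FPKM. Of 20 abscisic acid and dehydration genes 7 rose (7 adjusted over the list alone; median 0.48, camera adjusted p = 0.0120), a call lost without BPE replicate 2 (0.105). Of 18 xyloglucan endotransglucosylases 4 fell and 1 rose (5 and 1 adjusted over the list alone; median -0.92, camera adjusted p = 0.00184). Hypoxia genes fell in 5 of 15 cases (11 adjusted over the list alone; median -1.21, camera adjusted p = 1.16e-05) and lignin enzymes in 3 of 20 (3 adjusted over the list alone; median -0.36, camera adjusted p = 0.000447). For these 4 lists too, adjusted p = 0.538 with an estimated correlation. Cell cycle genes had a median of -0.54 with 2 of 28 lower (1 adjusted over the list alone; camera adjusted p = 2.00e-08, and adjusted p = 0.551 with an estimated correlation). The call of CYCB1;4 (AT2G26760), a B-type cyclin, was lost without any of the 6 libraries (0.0852 to 0.156). That of the kinase CDKB2;1 (AT1G76540) was lost without control replicate 1 (0.0636), control replicate 3 (0.0853), BPE replicate 1 (0.0738) or BPE replicate 2 (0.0883). Sulfur deficiency genes had a median of -0.67, and 1 of 13, the sulfate transporter SULTR1;1 (AT4G08620), fell (1 adjusted over the list alone; camera adjusted p = 0.0106, and adjusted p = 0.634 with an estimated correlation). Its fall lost its call without control replicate 3 or BPE replicate 2 (0.0572 each).

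Individual redox genes changed strongly with BPE. FSD1 (AT4G25100), an iron superoxide dismutase, rose from 6.10 ± 1.82 to 75.0 ± 41.3 FPKM and PRX34 (AT3G49120), a peroxidase, from 141 ± 31.6 to 797 ± 256 FPKM. Of 60 peroxidases 13 fell and 4 rose (15 and 6 adjusted over the list alone; median -0.21, camera adjusted p = 0.0378, and adjusted p = 0.592 with an estimated correlation). Quantile normalization (0.175), median scaling (0.140) or no filter on low values (0.0782) ended this call. The peroxidase call was also lost without control replicate 1 (0.0665), control replicate 3 (0.0783), BPE replicate 1 (0.264) or BPE replicate 2 (0.0516). The count of 2783 genes fell to 971 and 449 without control replicates 1 and 3, and to 659 and 705 without BPE replicates 1 and 2. It rose to 4943 when only these 6 libraries were fitted.

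In BPF roots, fewer genes changed, and single genes of superoxide removal and metal transport were among the strongest. The iron deficiency list, with 1 of 23 higher, and the intracellular scavenging list, with 1 higher and 2 lower of 37, were not called. FSD1 (AT4G25100) rose from 6.10 ± 1.82 to 146 ± 33.0 FPKM (SD, n = 3, log2 change 4.38, adjusted p = 0.000372), while CSD1 (AT1G08830), a copper and zinc superoxide dismutase, fell from 602 ± 48.0 to 229 ± 22.5 FPKM. ZIP2 (AT5G59520), a metal transporter, rose from 1.07 ± 0.0563 to 38.9 ± 11.6 FPKM. FRO4 (AT5G23980), a ferric reductase, rose from 0.0472 ± 0.0231 to 8.79 ± 3.1 FPKM, and the copper transporter COPT2 (AT3G46900) from 0.112 ± 0.0485 to 6.17 ± 2.55 FPKM. Of 9 flavonoid genes 3 fell (6 adjusted over the list alone; median -0.66, camera adjusted p = 1.17e-06), FLS1 (AT5G08640) from 61.5 ± 10.6 to 23.8 ± 7.96 FPKM. FLS1 lost its call without control replicate 1 (0.0776) or BPF replicate 3 (0.103). Of 18 xyloglucan endotransglucosylases 2 rose (7 adjusted over the list alone; median 0.90, camera adjusted p = 0.000190), and of 19 aquaporins 2 rose (7 rose and 1 fell adjusted over the list alone; median 0.35, camera adjusted p = 0.000290). For these 3 lists adjusted p = 0.626 with an estimated correlation. Calls of both xyloglucan genes were lost without control replicates 1, 2 and 3 and BPF replicates 2 and 3: XTH24 (AT4G30270) at 0.192, 0.0822, 0.0576, 0.0721 and 0.198, and XTH15 (AT4G14130) at 0.188, 0.111, 0.0814, 0.0997 and 0.279. XTH24 was also lost with only those 6 libraries (0.0567). CYP81D11 (AT3G28740) rose from 48.6 ± 4.21 to 151 ± 24.5 FPKM (0.0681 without BPF replicate 3).

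In 6 further lists that camera called with BPF, limma called 0 members over all 19484 genes (3500 of these genes had an unadjusted p below 0.05). Photosynthetic shoot markers had a median log2 change of 0.75 (6 of 26 higher adjusted over the list alone, camera adjusted p = 5.61e-08), and lignin enzymes one of -0.33 (2 of 20 lower adjusted over the list alone, camera adjusted p = 0.00379). Hypoxia genes had -0.61 (1 higher and 1 lower of 15 adjusted over the list alone, camera adjusted p = 0.00471), and salicylic acid genes 0.89 (2 of 10 higher adjusted over the list alone, camera adjusted p = 0.00471). The jasmonate list had 1.16 and the cell cycle list 0.19 (0 of 21 and 0 of 28 adjusted over the list alone, camera adjusted p = 0.0490 and 0.0461). For all 6 adjusted p = 0.731 with an estimated correlation. Omitting any of the 6 libraries moved the count of 270 genes, to 26, 60 and 125 without control replicates 1, 2 and 3, and to 625, 54 and 25 without BPF replicates 1, 2 and 3. With no filter on low values it was 173. The hypoxia call ended without BPF replicates 1 and 3 (0.0648 and 0.220), and the salicylic acid call without BPF replicate 2 (0.0927). The jasmonate call ended without control replicates 1 and 2 (0.0599 and 0.189) and without BPF replicates 2 and 3 (0.194 and 0.0525). The cell cycle call ended without control replicates 1 and 2 (0.0888 and 0.189) and without BPF replicates 1 and 2 (0.0648 and 0.368). Detoxification markers were called without control replicate 1 (0.0250) or BPF replicate 3 (0.0227), and peroxidases without control replicate 3 (0.0444).

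In BPS roots, genes of phosphate and sulfur shortage, wall loosening and water channels rose, and those of dehydration, cytokinin and hypoxia response fell. Phosphate starvation genes rose in 10 of 23 cases against 1 fall (16 and 1 adjusted over the list alone; median 1.67, camera adjusted p = 0.000487, and adjusted p = 0.572 with an estimated correlation). PHT1;5 (AT2G32830), a phosphate transporter, rose from 0.784 ± 0.374 to 5.42 ± 3.24 FPKM (SD, n = 3, log2 change 1.73, adjusted p = 0.0114, and 0.0583 without BPS replicate 2), and the ribonuclease RNS1 (AT2G02990) fell from 165 ± 52.0 to 19.8 ± 8.07 FPKM. Sulfur deficiency genes rose in 3 of 13 cases (8 adjusted over the list alone; median 1.4, camera adjusted p = 0.00385, and adjusted p = 0.572 with an estimated correlation), APR3 (AT4G21990) of sulfate reduction from 28.9 ± 1.71 to 80.5 ± 23.61 FPKM. XTH15 (AT4G14130) rose from 9.91 ± 1.13 to 55.9 ± 5.36 FPKM among 10 of 18 xyloglucan endotransglucosylases that rose against 1 that fell (12 and 1 adjusted over the list alone; median 1.29, camera adjusted p = 0.000707). Aquaporins rose in 12 of 19 cases with 1 fall (14 and 1 adjusted over the list alone; median 0.70, camera adjusted p = 0.000487). Photosynthetic shoot markers rose in 22 of 26 cases (25 adjusted over the list alone; median 1.53, camera adjusted p = 5.47e-11), PRK (AT1G32060) of the Calvin cycle from 0.793 ± 0.371 to 7.53 ± 2.55 FPKM. For these last 3 lists adjusted p = 0.353 with an estimated correlation. Cell cycle genes rose in 5 of 28 cases (4 adjusted over the list alone; median 0.48, camera adjusted p = 0.000521, and adjusted p = 0.592 with an estimated correlation).

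RD29A (AT5G52310) fell with BPS from 812 ± 175 to 30.8 ± 12.6 FPKM, and JOX4 (AT2G38240) from 382 ± 69.9 to 5.62 ± 8.96 FPKM. Of 20 abscisic acid and dehydration genes 7 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.35, camera adjusted p = 0.000487). The cytokinin response regulators ARR6 (AT5G62920) and ARR7 (AT1G19050) fell from 44.3 ± 7.28 to 13.9 ± 8.43 and from 60.6 ± 19.1 to 12.3 ± 4.36 FPKM, among 7 of 10 cytokinin genes that fell against 1 that rose (9 and 1 adjusted over the list alone; median -1.10, camera adjusted p = 0.000222). ADH1 (AT1G77120) fell from 313 ± 99.2 to 29.8 ± 11.7 FPKM in a hypoxia list with 9 of 15 lower (11 adjusted over the list alone; median -1.35, camera adjusted p = 2.56e-06). Heat shock genes fell in 6 of 14 cases with 1 rise (7 and 1 adjusted over the list alone; median -0.62, camera adjusted p = 0.00240), and flavonoid genes in 5 of 9 (5 adjusted over the list alone; median -0.66, camera adjusted p = 0.00190). For these 5 lists adjusted p = 0.353 with an estimated correlation. Lignin enzymes fell in 7 of 20 cases and rose in 2 (7 and 2 adjusted over the list alone; median -0.23, camera adjusted p = 0.00799, and adjusted p = 0.572 with an estimated correlation), a call lost after quantile normalization (0.0964) or without BPS replicate 3 (0.0501).

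Glutathione S-transferases fell with BPS in 11 of 37 cases and rose in 3 (12 and 4 adjusted over the list alone; median -0.17, camera adjusted p = 0.00779, and adjusted p = 0.353 with an estimated correlation). GSTU17 (AT1G10370) fell from 178 ± 55.7 to 9.32 ± 1.83 FPKM and GSTU4 (AT2G29460) from 198 ± 27.6 to 22.7 ± 12.4 FPKM. DIC2 (AT4G24570), a mitochondrial dicarboxylate carrier, rose from 11.4 ± 2.69 to 362 ± 212 FPKM, and ORA47 (AT1G74930), a transcription factor, from 4.76 ± 0.346 to 176 ± 131 FPKM. AT5G01710, a methyltransferase gene with the highest fitted rise here and in BPB, had values below 0.1 beside values above 20 within the BPA, BPE and BPF groups, as did 10 other genes, so its level is uncertain. The transferase call ended with quantile normalization (0.115), median scaling (0.0539) or without BPS replicate 3 (0.117). In that last case the median was 0.011. The count of 4094 genes fell to 2302 without control replicate 1. UDP-glucosyltransferases, not called with all libraries, were called lower without control replicate 2 (0.0433), and detoxification markers without control replicate 2 (0.0243), BPS replicate 1 (0.00926) or BPS replicate 2 (0.0421).

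Further settings changed calls of these lists. Fitting only the 6 libraries compared ended the calls of BPA aquaporins (adjusted p = 0.0637), BPB peroxidases (0.0545) and BPE peroxidases (0.05001). It added calls for BPF peroxidases (0.0268), BPF detoxification markers (0.0220), BPS UDP-glucosyltransferases (0.0285) and BPS detoxification markers (0.0281). Taking replicate number as a block ended the calls of BPA flavonoids and aquaporins (0.0552 each), BPB peroxidases (0.0516) and the BPF jasmonate list (0.0530), and added BPS detoxification markers (0.0269). Without a filter on low values the BPF jasmonate call ended (0.0744), and BPF detoxification markers (0.0283) and BPS UDP-glucosyltransferases (0.0444) were called. Quantile normalization ended the BPA calls of Casparian strip genes (0.0609) and flavonoids (0.119), and median scaling the latter (0.0929). Without members shared between lists, the calls of BPA flavonoids (0.0550), BPB peroxidases (0.0809), BPE peroxidases and BPE detoxification markers (0.135 each) ended. Without BPB replicate 3 and BPS replicate 3, those of BPA flavonoids (0.0654), BPA aquaporins (0.0968), the BPB jasmonate list (0.0994), BPB aquaporins (0.0772), BPS glutathione S-transferases (0.0853) and BPS lignin enzymes (0.0618) ended, and BPF detoxification markers were called (0.0316). Median scaling and the omission of both libraries were chosen after the data were seen.

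Member counts of called lists were checked after the data were seen. With 1 library omitted, some lists had 0 members called in their direction by limma. With BPA these were lignin enzymes (1 with all libraries) without control replicate 1 or BPA replicate 2, Casparian strip genes (1) without control replicates 1 or 3 or BPA replicates 2 or 3, and heat shock genes (2) without control replicate 3 or BPA replicate 2. With BPE they were peroxidases (13), phosphate starvation genes (5) and sulfur deficiency genes (1) without control replicate 3 or BPE replicate 2, and xyloglucan endotransglucosylases (4) without control replicate 3. Hypoxia genes (5) and cell cycle genes (2) joined them without control replicates 1 or 3 or BPE replicates 1 or 2. With BPF, beside the xyloglucan genes above, they were flavonoid genes (3) without control replicate 1 or BPF replicate 3, and aquaporins (2) without control replicates 1 or 3 or BPF replicate 3. With BPS they were phosphate starvation genes (10) without BPS replicate 2. The list medians kept their sign in all these cases.

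**Figure D3:**
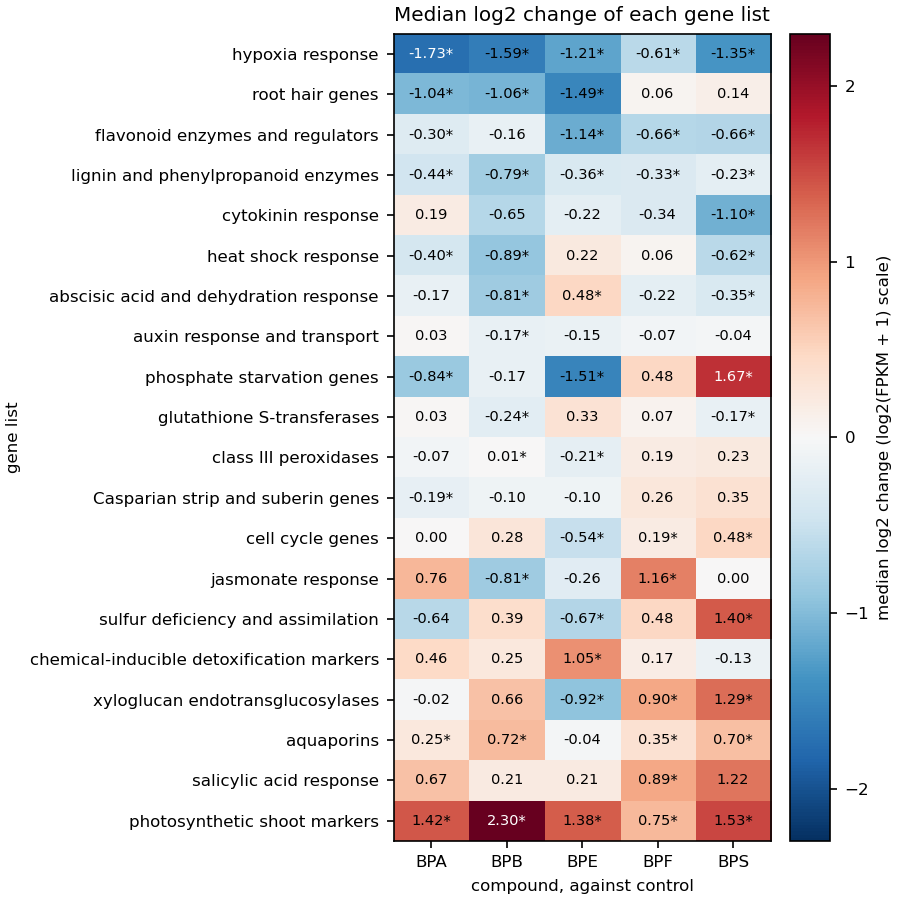
Median log2 change (log2(FPKM + 1) scale, colour and printed value) of the measured members of each gene list (y axis) for each compound against control (x axis); an asterisk marks lists that camera called at its preset correlation, and lists called in no comparison are left out. Hypoxia genes have a negative median with all 5 compounds, from -1.73 to -0.61, and photosynthetic shoot markers a positive one, from 0.75 to 2.30.

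Camera called 9 lists against control with none of the compounds. Intracellular scavenging enzymes of reactive oxygen had 37 measured members, of which 3 rose and 1 fell with BPA, 11 and 8 with BPB, 5 and 2 with BPE, 1 and 2 with BPF, and 6 and 6 with BPS. Of 8 NADPH oxidases, 1 fell with BPB (RBOHC, AT5G51060, 0.0769 without BPB replicate 2 and 0.0662 without control replicate 1) and 1 rose with BPE (RBOHA, AT5G07390, lost without any of its 6 libraries, at 0.0594 to 0.129, and after quantile normalization, at 0.0968). UDP-glucosyltransferases (29 measured) rose and fell in 2 and 2 cases with BPA, 5 and 5 with BPB, 8 and 4 with BPE, 2 and 1 with BPF, and 3 and 4 with BPS. Cytochrome P450s (143 measured) did so in 14 and 13, 37 and 25, 23 and 21, 4 and 3, and 29 and 21 cases. Iron deficiency genes (23 measured) rose in 6 cases with BPA, 12 with BPB, 2 with BPE, 1 with BPF and 5 with BPS, and fell in 0, 2, 4, 0 and 1. Nitrate genes (19 measured) rose in 3, 6, 3, 1 and 4 cases and fell in 1, 2, 3, 0 and 1. For ethylene genes (15 measured) these counts were 0, 3, 0, 0 and 4 higher and 5, 5, 2, 1 and 3 lower, and for brassinosteroid synthesis (7 measured) 0, 1, 0, 0 and 1 higher and 1, 1, 0, 0 and 1 lower. The only seed storage marker measured was OLEO4 (AT3G27660), an oleosin, which fell with BPS (log2 change -1.93).

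Some genes were called the same way with every compound. The 5 comparisons with control called 9475 genes in at least 1 case, and 45 genes were higher and 27 lower in all 5. All 5 use the same 3 controls, which by itself makes calls overlap. ZIP2 (AT5G59520) and CYP71B23 (AT3G26210) rose in all 5, CYP71B23 from 3.24 ± 1.2 FPKM in the control (SD, n = 3) to 16.0 ± 1.4 with BPA, 28.4 ± 1.4 with BPB, 21.2 ± 2.57 with BPE, 11.7 ± 2.02 with BPF and 18.9 ± 0.968 with BPS. GolS3 (AT1G09350), a galactinol synthase, and PAD3 (AT3G26830), a P450 of camalexin synthesis, fell in all 5, GolS3 from 46.9 ± 10.8 FPKM to between 1.93 ± 1.35 (BPB) and 13.0 ± 2.21 (BPE). The GolS3 call was lost without any of the 6 libraries with BPE (0.0679 to 0.121) and without control replicate 1 (0.144), control replicate 2 (0.0718), BPF replicate 2 (0.0687) or BPF replicate 3 (0.159) with BPF. The PAD3 call was lost without control replicate 1 (0.0851), control replicate 3 (0.101), BPE replicate 1 (0.0973) or BPE replicate 2 (0.0600) with BPE, and with BPF without control replicate 1 (0.152), control replicate 2 (0.0674), control replicate 3 (0.0758), BPF replicate 2 (0.0501) or BPF replicate 3 (0.159), or with only those 6 libraries (0.0575).

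Across genes, which are not independent replicates, the log2 changes of pairs of compounds had a mean correlation of 0.563, against 0.483 simulated for unchanged groups that share the controls. The highest simulated correlations, 0.88 to 0.931 by pair, lay above every observed one, so the correlation does not separate a shared response from shared controls. The mean covariance was 0.207 against 0.0409 simulated, and 7 of 10 pairs lay above the highest of their 100 draws. The others were BPA with BPF (0.181, highest draw 0.190), BPE with BPF (0.0828, 0.158) and BPE with BPS (0.0346, 0.193). BPB and BPS shared 1788 higher and 1247 lower genes, where independent lists, with controls not shared, would share 612 and 189, and had the highest correlation of the 10 pairs (0.780). BPE and BPS had the lowest (0.0894, against a simulated mean of 0.516, and a covariance below the simulated mean of 0.0421), with 396 shared higher, 182 shared lower and 116 opposite genes. The mean share of genes called in either of 2 comparisons that were called in both was 15.2%, and 7.85% without control replicate 1.

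**Figure D4:**
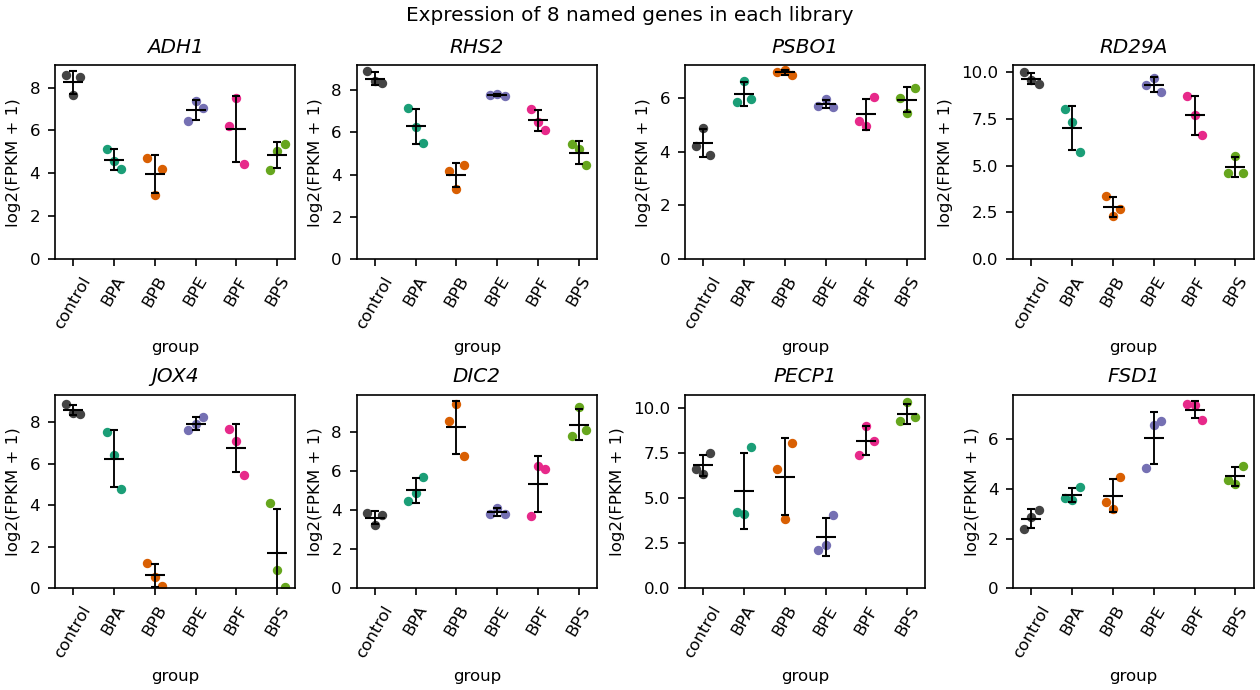
Expression of 8 genes, log2(FPKM + 1) on the y axis, in the 6 groups on the x axis; points are libraries, horizontal bars group means and whiskers the SD (n = 3). ADH1 lies at 8.24 in the control and 3.96 with BPB, JOX4 at 8.57 and 0.62, and FSD1 at 2.80 in the control and 7.17 with BPF. The panel titled PECP1 shows the locus AT1G73010.

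Genes annotated with oxidation reduction, the subject of the series, were tested as a further list that was chosen after the data were seen. Of 445 measured, 75 changed with BPA, 16.9% against 11.9% of annotated genes (one-sided Fisher's exact test, genes taken as independent, adjusted p = 0.00251). The share was 24.5% against 15.2% with BPE (adjusted p = 4.80e-07), 28.1% against 22.4% with BPS (0.00350), 40.0% against 37.9% with BPB (0.231) and 1.35% against 1.43% with BPF (0.617). By direction with BPE, lower genes were over-represented (11.5% against 6.18%, adjusted p = 0.00088 over all terms), and higher genes fell short (13.0% against 9.03%, adjusted p = 0.0651). The unadjusted p of the lower genes was 0.0506 without BPE replicate 2 and stayed below 0.05 without each other library. In all, 47 rose and 28 fell with BPA, 113 and 65 with BPB, 58 and 51 with BPE, 4 and 2 with BPF, and 80 and 45 with BPS, and camera called the list in none (adjusted p = 0.487 in all 5). Without control replicate 1, control replicate 3 or BPA replicate 2 the unadjusted p of BPA, 0.0010, was 0.596, 0.112 and 0.528, and that of BPF, 0.617, was 0.0465 without BPF replicate 3. For BPB, quantile normalization gave 0.0223 in place of 0.185.

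BPB against BPA, which differ by an ethyl in place of a methyl group on the bridge, gave 1937 genes, 1078 higher and 859 lower in BPB (799 and 995 with quantile normalization, 633 and 1112 with median scaling). JOX4 (AT2G38240) was lower in BPB, 0.615 ± 0.633 against 98.0 ± 79.4 FPKM (SD, n = 3, log2 difference -5.62, adjusted p = 0.00214), and ABR1 (AT5G64750), a transcription factor, at 3.26 ± 2.09 against 164 ± 114 FPKM. DLAH (AT1G30370), a lipase, was higher, 43.0 ± 19.4 against 3.23 ± 0.771 FPKM. Jasmonate genes were lower in 6 of 21 cases (10 adjusted over the list alone; median -1.71, camera adjusted p = 2.28e-11, and adjusted p = 0.319 with an estimated correlation) and glutathione S-transferases in 10 of 37 with 1 higher (15 and 2 adjusted over the list alone; median -0.22, camera adjusted p = 4.57e-06, and adjusted p = 0.0939 with an estimated correlation). Photosynthetic shoot markers were higher in 5 of 26 (6 adjusted over the list alone; median 0.81, camera adjusted p = 0.000154, and adjusted p = 0.641 with an estimated correlation). The 95% interval of the difference lay within 2-fold for 14544 of 19484 genes (74.6%). The count became 494 without BPA replicate 1, 728 without BPA replicate 2, 3235 without BPA replicate 3, 514 without BPB replicate 2, and 293 when only these 6 libraries were fitted.

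BPE against BPA, with 1 methyl group in place of 2 on the bridge, gave 512 genes, 358 higher and 154 lower in BPE. Flavonoid genes were lower in 5 of 9 cases (6 adjusted over the list alone; median -0.94, camera adjusted p = 5.48e-07, and adjusted p = 0.248 with an estimated correlation). Abscisic acid and dehydration genes were higher in 5 of 20 (10 adjusted over the list alone; median 0.87, camera adjusted p = 2.35e-08, and adjusted p = 0.245 with an estimated correlation). AT1G26380, of the berberine bridge enzyme family, was higher at 18.1 ± 2.15 against 1.64 ± 0.346 FPKM (SD, n = 3, log2 difference 2.86, adjusted p = 0.0107, but 0.0523 and 0.0536 without BPA replicates 2 and 3 and 0.0695 without BPE replicate 2). XTH19 (AT4G30290) was lower at 11.9 ± 3.02 against 85.2 ± 79.5 FPKM (adjusted p = 0.0320, but 0.0865 and 0.128 without BPA replicates 2 and 3 and 0.106 and 0.151 without BPE replicates 1 and 2, and 0.0769 with only these 6 libraries). For 15148 genes (77.7%) the interval of the difference lay within 2-fold. The count became 1185, 17 and 19 without BPA replicates 1, 2 and 3, 43 and 19 without BPE replicates 1 and 2, and 276 with only these 6 libraries.

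BPF against BPA, a methylene in place of the dimethyl carbon, gave 13 genes, 10 higher and 3 lower in BPF. By the naming rule, FSD1 (AT4G25100) was higher at 146 ± 33.0 against 12.7 ± 2.82 FPKM (SD, n = 3, log2 difference 3.42, adjusted p = 0.00523) and FRO4 (AT5G23980) at 8.79 ± 3.1 against 0.127 ± 0.0300 FPKM. CCS (AT1G12520), the copper chaperone of superoxide dismutase, and CSD2 (AT2G28190), a copper and zinc superoxide dismutase, were lower at 19.98 ± 4.75 against 46.6 ± 5.70 and 58.6 ± 8.24 against 123 ± 15.2 FPKM. The CCS call ended without BPA replicate 1 (0.0748), BPA replicate 2 (0.103), BPF replicate 1 (0.0543) or BPF replicate 2 (0.101), and that of CSD2 without BPA replicate 2 (0.103) or BPF replicate 2 (0.107). Both ended with only these 6 libraries (0.25 and 0.244). The other 9 were picked out after their values were seen: ZIP2 (log2 difference 2.22), COPT2 (2.4), the copper chaperone CCH (AT3G56240, 1.78), the microRNA locus MIR408 (AT2G47015, 1.89), the metal chelate transporter YSL2 (AT5G24380, 1.28), UMAMIT19 (AT1G21890, 1.75), AT1G71200 (2.31) and AT2G25625 (1.61) were higher and AT5G13720 (-0.90) was lower. In 15898 of 19484 genes (81.6%) the interval lay within 2-fold. Camera called 15 lists, though limma called 0 of their members over all genes (2649 genes had an unadjusted p below 0.05). Phosphate starvation genes had a median of 1.67 (18 of 23 higher adjusted over the list alone, camera adjusted p = 1.29e-13) and root hair genes of 1.06 (15 of 22, camera adjusted p = 1.42e-11), each with adjusted p = 0.228 with an estimated correlation. The count was 5, 7 and 42 without BPA replicates 1, 2 and 3, 8, 5 and 21 without BPF replicates 1, 2 and 3, 8 on the log2(FPKM + 0.1) scale and 2 with only these 6 libraries.

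BPS against BPA, a sulfonyl in place of the dimethyl carbon, gave 3554 genes, 2018 higher and 1536 lower in BPS. Phosphate starvation genes were higher in 19 of 23 cases (22 adjusted over the list alone; median 2.75, camera adjusted p = 3.82e-11), and sulfur deficiency genes in 10 of 13 (12 adjusted over the list alone; median 1.58, camera adjusted p = 1.51e-05), both with adjusted p = 0.495 with an estimated correlation. MGD3 (AT2G11810), a galactolipid synthase, was higher at 142 ± 61.4 against 9.23 ± 13.1 FPKM (SD, n = 3, log2 difference 4.62, adjusted p = 0.0135, but 0.0630 and 0.0771 without BPA replicates 1 and 2 and 0.0596 without BPS replicate 2). ABR1 (AT5G64750) was lower at 6.87 ± 8.48 against 164 ± 114 FPKM (log2 difference -4.61). Its call, like those of the 3 other genes that the rule names here, was lost when only these 6 libraries were fitted (0.0699 to 0.0760), which left 3 genes in all. Omissions gave 656, 580 and 5745 genes without BPA replicates 1, 2 and 3 and 848 and 1626 without BPS replicates 2 and 3. In all, 13790 genes (70.8%) had intervals within 2-fold.

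BPE against BPB, with a single methyl in place of a methyl and an ethyl group, gave 6107 genes, 2279 higher and 3828 lower in BPE (3047 and 2796 with median scaling). RD29A (AT5G52310) stood at 650.5 ± 175 against 6.19 ± 2.75 FPKM (SD, n = 3, log2 difference 6.54, adjusted p = 1.41e-05) and JOX4 (AT2G38240) at 246 ± 53.3 against 0.615 ± 0.633 FPKM. Abscisic acid and dehydration genes were higher in 13 of 20 cases (16 adjusted over the list alone; median 2.02, camera adjusted p = 1.93e-13), and this list alone stayed called with an estimated correlation, at adjusted p = 0.0455. Cell cycle genes were lower in 24 of 28 (26 adjusted over the list alone; median -0.82, camera adjusted p = 1.09e-06, and adjusted p = 0.484 with an estimated correlation). Glutathione S-transferases were higher in 18 of 37 and lower in 4 (21 and 5 adjusted over the list alone; median 0.59, camera adjusted p = 1.86e-06, and adjusted p = 0.0799 with an estimated correlation), and photosynthetic shoot markers lower in 14 of 26 (17 adjusted over the list alone; median -0.94, camera adjusted p = 0.000733, and adjusted p = 0.665 with an estimated correlation). The count was 3605 without BPE replicate 2. Intervals lay within 2-fold for 13013 genes (66.8%).

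BPF against BPB, a methylene in place of the carbon with a methyl and an ethyl group, gave 5448 genes, 1518 higher and 3930 lower in BPF (2186 and 2111 with median scaling). ABR1 (AT5G64750) stood at 199 ± 102 against 3.26 ± 2.09 FPKM (SD, n = 3, log2 difference 5.52, adjusted p = 0.000377), and ERF104 (AT5G61600), an ethylene response factor, at 26.3 ± 11.0 against 304 ± 140 FPKM. Root hair genes were higher in 12 of 22 cases (16 adjusted over the list alone; median 1.25, camera adjusted p = 4.69e-10), hypoxia genes in 9 of 15 (11 adjusted over the list alone; median 1.5, camera adjusted p = 4.69e-08) and jasmonate genes in 9 of 21 (11 adjusted over the list alone; median 1.79, camera adjusted p = 7.01e-10). Each of the 3 had adjusted p = 0.242 with an estimated correlation. Photosynthetic shoot markers were lower in 19 of 26 (26 adjusted over the list alone; median -1.47, camera adjusted p = 4.69e-08, and adjusted p = 0.426 with an estimated correlation). The count was 2324 without BPB replicate 2, 2566 without BPF replicate 2 and 2635 with only these 6 libraries. Intervals lay within 2-fold for 13517 genes (69.4%).

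BPS against BPB, a sulfonyl in place of the carbon with a methyl and an ethyl group, gave 1800 genes, 517 higher and 1283 lower in BPS (754 and 713 with median scaling). Phosphate starvation genes were higher in 5 of 23 cases (22 adjusted over the list alone; median 1.84, camera adjusted p = 9.12e-14) and root hair genes in 8 of 22 (19 adjusted over the list alone; median 1.23, camera adjusted p = 1.18e-12), both with adjusted p = 0.282 with an estimated correlation. Photosynthetic shoot markers were lower in 1 of 26 (1 adjusted over the list alone; median -0.72, camera adjusted p = 0.00148, and adjusted p = 0.602 with an estimated correlation), a call lost without BPS replicate 2 (0.180). NRT2.1 (AT1G08090) stood at 61.6 ± 51.8 against 2.09 ± 1.44 FPKM (SD, n = 3, log2 difference 4.07, adjusted p = 0.0240) and lost its call without BPB replicate 1 (0.0681), BPB replicate 2 (0.160) or BPS replicate 2 (0.133), and with only these 6 libraries (0.141). The count was 17 and 3744 without BPB replicates 1 and 3, 914 without BPS replicate 1, and 3422 without both BPB replicate 3 and BPS replicate 3, a setting added after the data were seen. It was 0 by limma without BPB replicate 2 (3328 genes at an unadjusted p below 0.05), without BPS replicate 2 (3847) and with only these 6 libraries (3980). Intervals lay within 2-fold for 14691 genes (75.4%).

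BPF against BPE, a methylene in place of a carbon with 1 methyl group, gave 3108 genes, 1294 higher and 1814 lower in BPF (1778 and 1750 with median scaling). Root hair genes were higher in 17 of 22 cases (19 rose and 1 fell adjusted over the list alone; median 1.4, camera adjusted p = 1.75e-09), phosphate starvation genes in 15 of 23 (20 adjusted over the list alone; median 1.93, camera adjusted p = 8.48e-11) and cell cycle genes in 16 of 28 (22 adjusted over the list alone; median 0.74, camera adjusted p = 1.20e-11). For all 3 adjusted p = 0.481 with an estimated correlation. AT1G73010, a phosphatase of phosphate starvation, stood at 325 ± 178 against 7.87 ± 6.99 FPKM (SD, n = 3, log2 difference 5.33, adjusted p = 0.00988, but 0.0531 without BPE replicate 1 and 0.0642 without BPF replicate 2). AT1G26390, of the berberine bridge enzyme family, stood at 0.629 ± 0.183 against 19.7 ± 11.3 FPKM (0.0550 without BPF replicate 2). The count fell to 224 and 284 without BPE replicates 1 and 2, to 50 without BPF replicate 2 and to 1908 without BPF replicate 3. Intervals lay within 2-fold for 14031 genes (72.0%).

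BPS against BPE, a sulfonyl in place of a carbon with 1 methyl group, gave 7686 genes, 4058 higher and 3628 lower in BPS (3910 and 4255 with quantile normalization), the most of any pair. AT1G73010 stood at 887 ± 366 against 7.87 ± 6.99 FPKM (SD, n = 3, log2 difference 6.85, adjusted p = 0.000277), and AT5G54300, of a family with a domain of unknown function, at 3.00 ± 1.04 against 282 ± 59.8 FPKM. Phosphate starvation genes were higher in 21 of 23 cases (22 adjusted over the list alone; median 2.73, camera adjusted p = 2.22e-09, and adjusted p = 0.436 with an estimated correlation) and cell cycle genes in 25 of 28 (27 adjusted over the list alone; median 1.03, camera adjusted p = 1.15e-09, and adjusted p = 0.451 with an estimated correlation). Xyloglucan endotransglucosylases were higher in 15 of 18 (15 adjusted over the list alone; median 2.19, camera adjusted p = 5.87e-06) and detoxification markers lower in 12 of 18 and higher in 3 (13 and 3 adjusted over the list alone; median -1.42, camera adjusted p = 0.000103, but 0.192 without members shared with other lists), both with adjusted p = 0.386 with an estimated correlation. Intervals lay within 2-fold for 12357 genes (63.4%).

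BPS against BPF, a sulfonyl in place of a methylene, gave 593 genes, 204 higher and 389 lower in BPS. JOX4 (AT2G38240) stood at 5.62 ± 8.96 against 127 ± 80.02 FPKM (SD, n = 3, log2 difference -5.07, adjusted p = 0.00757, but 0.0566 without BPF replicate 1 and 0.0501 without BPS replicate 2), and DLAH (AT1G30370) at 45.9 ± 31.6 against 3.5 ± 1.89 FPKM. Glutathione S-transferases were lower in 8 of 37 cases (14 fell and 3 rose adjusted over the list alone; median -0.20, camera adjusted p = 3.05e-06, and adjusted p = 0.0895 with an estimated correlation), and heat shock genes in 4 of 14 (6 and 1 adjusted over the list alone; median -0.65, camera adjusted p = 6.26e-07, and adjusted p = 0.0895 with an estimated correlation). Photosynthetic shoot markers were higher in 2 of 26 (4 adjusted over the list alone; median 0.62, camera adjusted p = 4.67e-06, and adjusted p = 0.548 with an estimated correlation). The count was 57 and 252 without BPF replicates 1 and 2, 1652, 98 and 103 without BPS replicates 1, 2 and 3, and 281 without both BPB replicate 3 and BPS replicate 3. It was 8 with only these 6 libraries, which ended the calls of JOX4 (0.114) and DLAH (0.104). For 15147 genes (77.7%) the interval lay within 2-fold.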

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

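Median scaling, the omission of BPB replicate 3 with BPS replicate 3, all alternatives of the oxidation-reduction list, the permutation of replicate numbers, and the quantile and single-library alternatives of the shared response were tests chosen after the results were seen. Counts of genes by limma stayed within 1.5 times in all 15 comparisons with quantile normalization, median scaling, no intensity trend or replicate number as a block. Of 299 results for named genes, 200 held under each alternative run for them. At least 1 omission ended 95 calls, only the 6 libraries compared 25, the block 3, quantile normalization 2 and no trend 0. None reversed in direction, and no other alternative was run. The 228 list results were 54 calls against control, 144 between compounds and redox lists not called against control. An estimated correlation ended 197 calls, removing shared members 17, median scaling 16 and quantile normalization 15. The block ended 6, no filter 5, only the 6 libraries 4, and omitting BPB replicate 3 with BPS replicate 3 19. Over 1368 list results with 1 library omitted, 122 lost a call and 9 gained one.

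A 2-fold threshold, which by construction keeps fewer genes, left 813 genes for BPA, 2658 for BPB, 1129 for BPE, 160 for BPF and 1701 for BPS against control. It left 765, 275 and 1458 for BPB, BPE and BPS against BPA, and 1979, 1484 and 535 for BPE, BPF and BPS against BPB. It left 1153 for BPF against BPE, 2996 for BPS against BPE and 361 for BPS against BPF. With only the 6 libraries compared, BPE against control gave 4943, BPB against BPA 293, BPE against BPA 276, BPF against BPA 2, BPS against BPA 3, BPF against BPB 2635, BPS against BPF 8 and BPS against BPB 0 by limma (3980 at an unadjusted p below 0.05). With fewer libraries the spread is estimated on fewer degrees of freedom, and the cause of each single move was not tested. No filter gave 173 for BPF against control, and log2(FPKM + 0.1) gave 8 for BPF against BPA. Without BPB replicate 3 and BPS replicate 3, BPS against BPB gave 3422 and BPS against BPF 281. For these 4 the cause was not tested.

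With 1 library left out, counts against control ran from 245 to 2112 for BPA, 4990 to 7440 for BPB, 449 to 2489 for BPE, 25 to 625 for BPF and 2302 to 3989 for BPS. For pairs with BPA they ran from 494 to 3235 for BPB, 17 to 1185 for BPE, 5 to 42 for BPF and 580 to 5745 for BPS. Against BPB they ran from 3605 to 5701 for BPE, 2324 to 5379 for BPF and 0 to 3744 for BPS. The count of 0 came from limma without BPB replicate 2 (3328 at an unadjusted p below 0.05) and without BPS replicate 2 (3847). The ranges were 50 to 2797 for BPF against BPE, 5566 to 7133 for BPS against BPE and 57 to 1652 for BPS against BPF. In 51 of these 90 fits the count moved by more than 1.5 times, and the cause was not tested. List calls against control ran from 52 to 58 and between compounds from 138 to 148. The shared response ran from 7.85% to 18.4%, and its correlation from 0.524 to 0.609.

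With an estimated correlation, camera called 0 of the 54 list results against control and 1 of the 144 between compounds, abscisic acid and dehydration genes in BPE against BPB. The cause was not tested. As a share of genes with the same sign, the shared response was 85.6%, a different measure by construction. Simulated unchanged groups gave 94.3% to 99.97% on it, from the 5 to 9 draws per pair with any call, so 85.6% is no sign of a shared response.

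Scaling moved the balance of directions more than the counts. The median change of all genes in BPB against control moved by -0.13 log2 with quantile normalization and -0.18 with median scaling. The higher and lower genes with quantile normalization were 892 and 939 for BPA (1281 and 746 as reported), 3476 and 2935 for BPB (4973 and 2164), 1409 and 1261 for BPE (1770 and 1013), 117 and 190 for BPF (138 and 132) and 1852 and 2333 for BPS (2396 and 1698). With median scaling they were 1039 and 1179, 3227 and 3581, 1422 and 1729, 134 and 198, and 1923 and 2463 in the same order. For pairs, median scaling turned the larger direction for BPB against BPA (633 higher and 1112 lower), BPE against BPB (3047 and 2796), BPF against BPB (2186 and 2111), BPS against BPB (754 and 713) and BPF against BPE (1778 and 1750). It also turned for BPB against BPA with quantile normalization (799 and 995) and for BPF against BPE with only the 6 libraries (2115 and 1951). For BPS against BPE it turned with quantile normalization (3910 and 4255), without BPS replicate 3 (3030 and 3645) and without BPB replicate 3 and BPS replicate 3 (3538 and 3901). With only the 6 libraries it turned for BPB, BPE and BPS against BPA, and with a 2-fold threshold for BPB against BPA, BPE, BPF and BPS against BPB, and BPF against BPE. Single omissions turned it for BPF against control, BPB, BPF and BPS against BPA, and BPS against BPF. Without counts or an added standard, no value decides which scaling is nearer to the truth.

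Replicate numbers were checked before replicate number was read as a block. Over 45 pairs of libraries with the same number in different groups, deviations from the group means correlated at -0.566 to 0.648 (mean 0.0231). Of 7776 ways to number the compound libraries, 2257 gave as high a mean (exact permutation p = 0.290). For 9 of 18 libraries the mean correlation by number was highest with their own. By number, control with BPA (mean 0.336, next 0.195) and BPA with BPB (0.237, next 0.222) were higher than in the 5 other matchings, so a pairing of these groups is not excluded. The block fit, an alternative only, gave 1977 (BPA) and 7286 (BPB) genes against control and 2053 for BPB against BPA. Depth bears on genes near 1 FPKM (23.9 to 33.3 fragments on a 1.5 kb transcript).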

Other observations

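The shoot list outside photosynthesis and both wound gene lists, the tests of shoot tissue, of exchanged or doubled libraries, of cutting time and of scaling were all chosen after the results they bear on were seen. Only the splits of the libraries were planned.

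Annotation terms were tested on the same calls by one-sided Fisher's exact tests, which take genes, not libraries, as independent. Of annotated genes 7.70%, 25.7%, 9.03% and 13.4% were higher with BPA, BPB, BPE and BPS. Photosynthesis was over-represented among these (24, 47, 29 and 31 of 58 genes, adjusted p = 4.24e-10, 4.38e-16, 2.36e-13 and 1.34e-10). Defense response was so with BPA (47 of 224, 2.18e-08) and BPB (88, 0.000370), and protein phosphorylation with BPS (126 of 642, 0.000321). Among lower genes, response to salt stress stood out with BPA (25 of 233, 0.000815), BPB (59, 2.61e-06) and BPS (42, 0.000585). Drug transmembrane transport did so with BPA (8 of 40, 0.0099), BPB (12, 0.0392), BPF (6, 0.000134) and BPS (12, 0.00454). Cell wall organization did so with BPE (9 of 22, 0.000315). In all, 5, 10, 6, 0 and 6 terms passed for higher genes and 3, 8, 5, 2 and 8 for lower genes with BPA, BPB, BPE, BPF and BPS.

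Photosynthetic shoot markers had a positive median with all 5 compounds, the highest in BPB, 2.30. With BPF limma called 0 of 26 over all genes, and with an estimated correlation camera called the list with no compound (adjusted p = 0.353 to 0.731). Shoot tissue among the roots would bring other leaf transcripts along, but the median change of 7 measured shoot genes outside photosynthesis in BPB was 0.0585 (95% bootstrap interval -0.05 to 0.43), below 1.15, which is 50% of 2.30 and the bound set for it. Of these 7, CER3 rose (4.85 to 7.22 FPKM), and TGG1, too low to be tested, went from 0.127 to 0.854 FPKM, so a small share of shoot cells is not ruled out. Scaling alone is argued against by the median of 2.16 after quantile normalization. No biological explanation was tested.

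BPB replicate 3 and BPS replicate 3 deviated from their groups in the same direction, with the highest correlation of deviations (0.648) among 135 pairs of libraries, the next being 0.584. A single library under both labels is argued against by a mean chi-square per gene of 30.5 between them, where libraries of 1 group had 12.8 to 159. Each was nearer to the other than to its own group: BPB replicate 3 had 159 and 127 to BPB replicates 1 and 2, and BPS replicate 3 had 124 and 84.0 to BPS replicates 1 and 2. The value excludes a doubled file only, not 2 preparations of 1 RNA. On an axis from BPB (0) to BPS (1) over 1841 genes, BPS replicate 3 lay at 0.841 (0.814 to 0.869). BPB replicate 3 lay at 0.525 (0.494 to 0.552). The controls lay at 0.672 to 0.988, so the axis is not specific to BPS. Whether BPS replicate 3 is a BPB library, or BPB replicate 3 a BPS library, could not be decided. A condition shared by both libraries, such as a plate or a day, may also lie behind it and is not in the labels. No biological explanation was tested.

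Early touch and wound genes were higher and late wound genes lower in BPB and BPS. Of 18 early genes 13 rose in each (medians 2.77 and 2.92), and of 12 late genes measured 9 fell in BPB and 8 in BPS (medians -3.88 and -3.58). The early list rose in 0 cases and fell in 1 with BPA (median 1.58), and in 0 and 0 with BPE (0.38) and BPF (1.71). The late list had 0 higher and 1 lower with BPA (-0.76), and 0 and 0 with BPE (-0.45) and BPF (-0.46). The shoot list outside photosynthesis had medians of -0.15, -0.14, 0.21 and 0.30 with BPA, BPE, BPF and BPS, and 1 gene higher with BPE.

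Among members, CAF1A, of messenger RNA deadenylation, went from 15.1 FPKM in the control to 400.0 in BPB and 372 in BPS, and ABR1 from 427 to 3.26 and 6.87. Of the early and late members, 3 and 6 also belong to the fixed lists. Scaling alone is argued against by the late median of -3.81 in BPB after quantile normalization. Control roots that lay longer between cutting and freezing may have passed from early to late wound genes, a candidate explanation from handling. Within groups, early and late scores had r = 0.136 over 18 libraries (two-sided permutation p = 0.690; Spearman rho = -0.100, permutation p = 0.764; r = -0.0167 without the 2 libraries farthest from the median), which neither shows nor excludes it. Handling time and compound cannot be told apart for these genes, since the labels give no times of handling.

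The 6 libraries of a comparison can be split into groups of 3 in 10 ways, too few for a share below 0.05. The real split, 1 of 10 as large, gave 2027 genes for BPA, 7137 for BPB, 2783 for BPE, 270 for BPF and 4094 for BPS against control, and the highest other split 1, 0, 0, 0 and 0. For BPE against BPA the real value was 512 and the highest other 0, for BPS against BPA 3554 and 0, for BPE against BPB 6107 and 0, and for BPF against BPB 5448 and 136. They were 3108 and 0 for BPF against BPE, 7686 and 3 for BPS against BPE, and 593 and 0 for BPS against BPF. In BPB against BPA 1937 genes stood beside 1418 when BPA replicates 1 and 2 joined BPB replicate 1. In BPS against BPB 1800 stood beside 1698 when BPB replicates 1 and 2 joined BPS replicate 1. In BPF against BPA 2 of the 10 splits gave as many genes as the real 13, and the higher one, 80, joined BPA replicates 1 and 2 with BPF replicate 1. The cause of these 3 was not tested.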
